A study of Mus musculus with 3 samples.

How the data were processed

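LACE-seq was performed on MTR4 in 3 samples of KIT-positive cells sorted by flow cytometry from testes of mice at postnatal day 8, with the wild-type Mtr4 genotype, per the labels. Cells were irradiated with ultraviolet C light at 400 mJ, lysed and treated with DNase, and the precipitated RNA was fragmented with micrococcal nuclease, reverse transcribed, tailed, amplified and sequenced, per the labels' protocols. Nothing in the labels says whether the 3 samples came from separate animals or pools. All 3 samples formed 1 group, and none was a control precipitation or an input library.

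The submitters' processing notes name cutadapt 1.15, Bowtie 1.0.0 and the mouse build mm10. No label states the peak caller, its settings, any removal of duplicate reads or any pooling of replicates. The deposited name of the list reads as if replicates were merged, duplicates removed and peaks called with Piranha, which was not checked. As deposited by the authors, the list has 4 columns and no header: chromosome, start, end and strand. It holds no score, read count, fold enrichment or p-value, so peaks could be neither ranked nor filtered by strength, and depth per sample is unknown. All coordinates are multiples of 20 nt, so a peak is placed no more finely than that. The list is recorded under replicate 3; no list of replicates 1 and 2 was analysed here. It had no peak on the mitochondrial chromosome. Coordinates are given 1-based on mm10.

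Peaks were joined by their midpoint to the RefSeq gene table of assembly GRCm38.p6, whose chromosomes are those of mm10. That table lists 49943 genes with start, end and biotype, of which 21887 are protein-coding and 12727 long noncoding; it gives no strand, exon or sequence. Peaks were therefore counted in gene bodies on either strand, and a peak inside nested or overlapping genes counted for each of them. Planned tests that need strand, exons, a score or a genome were not run: genomic class, sense against antisense, first intron, distance to exon ends, repeats, sequence composition and score by class. The planned test of the upstream antisense region was replaced by a Fisher's exact test of side against sign in the 3000 nt beyond each protein-coding gene. The sign in the file is opposite to the known orientation of the genes checked (Malat1, Neat1, Actb, Fosb, Fos, Egr1 and Ubb), so transcript direction was read against the sign; the gene table could not settle this for other genes.

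Each peak was redrawn 1000 times at a uniform position on its chromosome between the first and last annotated gene or peak, which gave expected numbers and 2-sided empirical p-values with a smallest value of 0.0020; these and the p-values from random lists are given as permutation p. Numbers per chromosome were set against 10000 draws of all peaks over chromosomes by their size, with the p-value likewise called a permutation p. Unsequenced and unmappable bases could not be left out of the redraws, which can lift the apparent share of peaks in genes. Gene lists, 18 in number with 553 names, were fixed before the data were examined; 549 names matched the table, 5 of them through a synonym, and 4 did not match. The share of protein-coding members with a peak was set against 10000 random lists matched on gene length in 20 classes, with Benjamini-Hochberg adjustment over 16 lists; lists of noncoding genes were described only. Genes with an excess of peaks were found with a 1-sided exact Poisson test against the higher of the chromosome density and the density within 500 kb on either side, adjusted over 34614 genes; the threshold was an adjusted p of 0.05. This test, the test of peaks near gene ends and the test of the sign were chosen after the data had been seen. Shares have 95% Wilson intervals.

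Genes were named by a rule set in advance: Mtrex; the 10 genes with the most peaks; the 5 noncoding genes with the most peaks; and from each list the 4 members with the most peaks. A planned part on the highest-scoring peaks was replaced by the 10 widest peaks and the 10 densest windows of 100 kb, and ties were settled by summed peak width in place of score. Of the genes the rule names, 1 is not reported here, nor drawn in the plot of peaks per gene; it stays in the counts over all genes. Genes outside the rule are said to be so where they appear.

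Methods were tested on simulated data. Uniformly placed peaks gave a genic excess of 0.997-fold, and an odds ratio planted at 1.5 was recovered as 1.49. With uniform peaks, 0 of 34614 genes passed the Poisson test. With 3, 5 or 8 peaks added to each of 200 genes, 27.5%, 97.0% and 100% of them passed, so a gene with 3 extra peaks is often missed. The real peaks were not uniform: protein-coding genes of up to 5 kb held 45.8 per Mb, against 5.83 over all chromosomes. The simulation therefore cannot show how many short genes pass through that density alone. Random lists gave p under 0.05 in 5.50% of draws.

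Alternatives fixed in advance were the merging of peaks of 1 sign less than 100 nt apart, other overlap rules, flanks of 1000 and 5000 nt, leaving out the 10 genes with the most peaks, requiring 2 peaks, lists not matched on length, and genic peaks per chromosome. Added after seeing the data were peaks of 40 nt or more in place of a stricter threshold, each sign alone, leaving out peaks in small RNA genes or within 1 kb of them, gene lists drawn from genes with no small RNA gene within 1 kb, shifting all peaks of a chromosome together, end windows of 500 and 2000 nt, and the chromosome density alone as background. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.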

Results

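RNA that precipitated with MTR4 was mapped in KIT-positive cells sorted from the testes of mice at postnatal day 8. MTR4, encoded by Mtrex, is the helicase that delivers nuclear RNA to the exosome. The sort was aimed at differentiating spermatogonia, the germ cells that precede meiosis, and the question was which transcripts MTR4 contacts in them. The assay was LACE-seq, in which RNA crosslinked to a protein by ultraviolet light is precipitated with an antibody and the ends of the reverse-transcribed fragments mark the contact sites. The 3 samples formed 1 group, and no control precipitation was among them, so no comparison between groups was made. For the same reason, background from abundant RNA could not be separated from contacts of MTR4. Results rest on 1 list of peaks, recorded under replicate 3; no list of replicates 1 and 2 was analysed here. No label says whether the list pools the replicates; its deposited name reads as if it does, which was not checked. It held 15769 peaks, 5.83 per Mb, each with a position and a strand sign but no score or read count, so the sequencing depth behind a peak is unknown. A width of 20 nt was found for 15093 peaks (95.7%), and 676 (4.29%) were 40 nt or wider, up to 760 nt. Every p-value compares positions or genes within this list and has no replicate check. Intervals are 95% Wilson intervals that cover counting error only.

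Peaks piled up on a small set of transcripts, led by Malat1 and immediate early genes, but most peaks lay elsewhere. The 93 genes that passed the test below held 451 of the 15769 peaks, and 5390 of the 7575 genes with a peak held 1. Malat1, an abundant nuclear long noncoding RNA (mm10 chromosome 19, 5795690 to 5802672), carried 28 peaks, 143-fold more than expected from its length and the local peak density. Next came the immediate early transcription factor genes Fosb (chromosome 7, 19302696 to 19310118) with 19 peaks, 107-fold over expectation, and Egr1 (chromosome 18, 34861207 to 34864956) with 13, 289-fold over it. Adjusted p was 1.3e-45 for Malat1, 7.0e-28 for Fosb and 5.5e-24 for Egr1 (1-sided exact Poisson test, Benjamini-Hochberg over 34614 protein-coding and long noncoding genes). The folds of Malat1, Fosb and Egr1 depended on the settings: they were 521, 394 and 639 with the chromosome density alone as background, and 81.8, 78.6 and 178 with peaks of 1 sign less than 100 nt apart merged. In all, 93 genes passed this test, 68 protein-coding and 25 long noncoding, with a median length of 5.68 kb against 34.2 kb for the genes with a peak. This contrast is partly built in, since expected numbers grow with length and longer genes hold a peak more often. All peaks of a gene shared 1 sign in 66 of the 93. Among those outside the naming rule, and picked after their values were seen, were Ubb with 8 peaks, Actb with 9, Fos with 7 and Nr4a1 with 8. Of the 93, 25 had a peak inside a nested small RNA gene, and 23 of these no longer passed without such peaks. The folds left to those 23 ran from 0 for Nop58, Hspa8 and Gm26232 to 237 for 5730408K05Rik, which kept 1 peak, so some lost all excess and others too many peaks to pass; of these 4, all but Nop58 were picked after their values were seen. The number of genes that passed fell to 53 when peaks of 1 sign less than 100 nt apart were merged. Expression is not given, so transcript abundance was not held fixed.

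**Figure D1:**
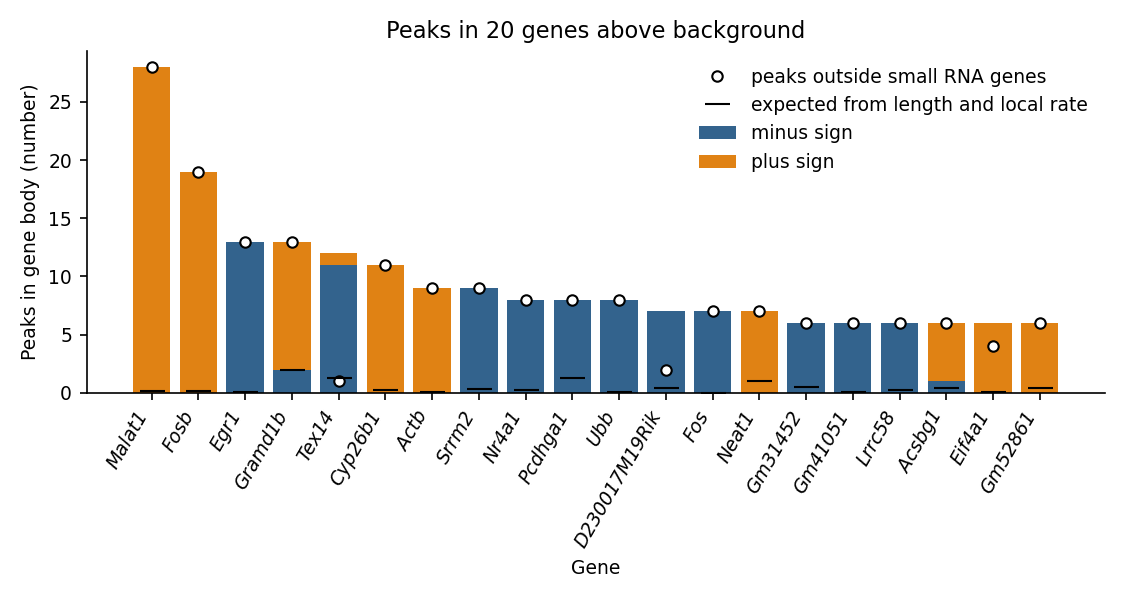
Number of peaks in the gene body (vertical axis) for 20 of the 93 genes above background, taken from those with the most peaks, with bars stacked by the strand sign in the file, a circle at the number of peaks outside small RNA genes and a black line at the number expected from length and local density. Malat1 stands highest with 28 peaks, most bars are of a single colour, and the circle of Tex14 lies at 1 of its 12 peaks.

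Among the listed genes of germ cells and retinoic acid metabolism, Cyp26b1 stood out, though which testis cells its peaks came from was not tested. This gene, which encodes an enzyme that degrades retinoic acid (chromosome 6, 84571414 to 84593908), carried 11 peaks, all with the plus sign and none near a small RNA gene, 54.3-fold over expectation (adjusted exact Poisson p = 2.4e-12) and 85.7-fold with the chromosome density alone. Tex14 (chromosome 11, 87405013 to 87555823) encodes a component of the bridges between germ cells. It held 12 peaks, 9.65-fold over expectation (adjusted exact Poisson p = 2.0e-05), but 11 of them lay in small RNA genes inside it. These were 3 in Gm22068, 2 each in the U1 gene Rnu1a1 and the U3 gene Rnu3b3, and 1 each in Rnu3b1, Rnu3b2, Rnu3b4 and Gm23137. Without peaks in small RNA genes Tex14 kept 1 peak, 0.829-fold of expectation (adjusted exact Poisson p = 1), so no excess on Tex14 itself was found. Gramd1b (chromosome 9, 40293233 to 40533614) held 13 peaks over 240 kb, 6.76-fold over expectation (adjusted exact Poisson p = 0.00017). Also among the 10 genes with the most peaks, Gm37013, Gm38666 and Gm38667 are overlapping gene models of chromosome 18 that share the same 10 peaks over 868 kb to 889 kb, and none passed (1.41-fold to 1.44-fold, adjusted exact Poisson p = 1). Mtrex itself (chromosome 13, 112867780 to 112927380) held 0 peaks where 0.72 were expected, so an absence of binding was not detectable at this depth. Exons and introns of these genes were not told apart, since the gene table used gives only gene starts and ends.

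**Figure D2:**
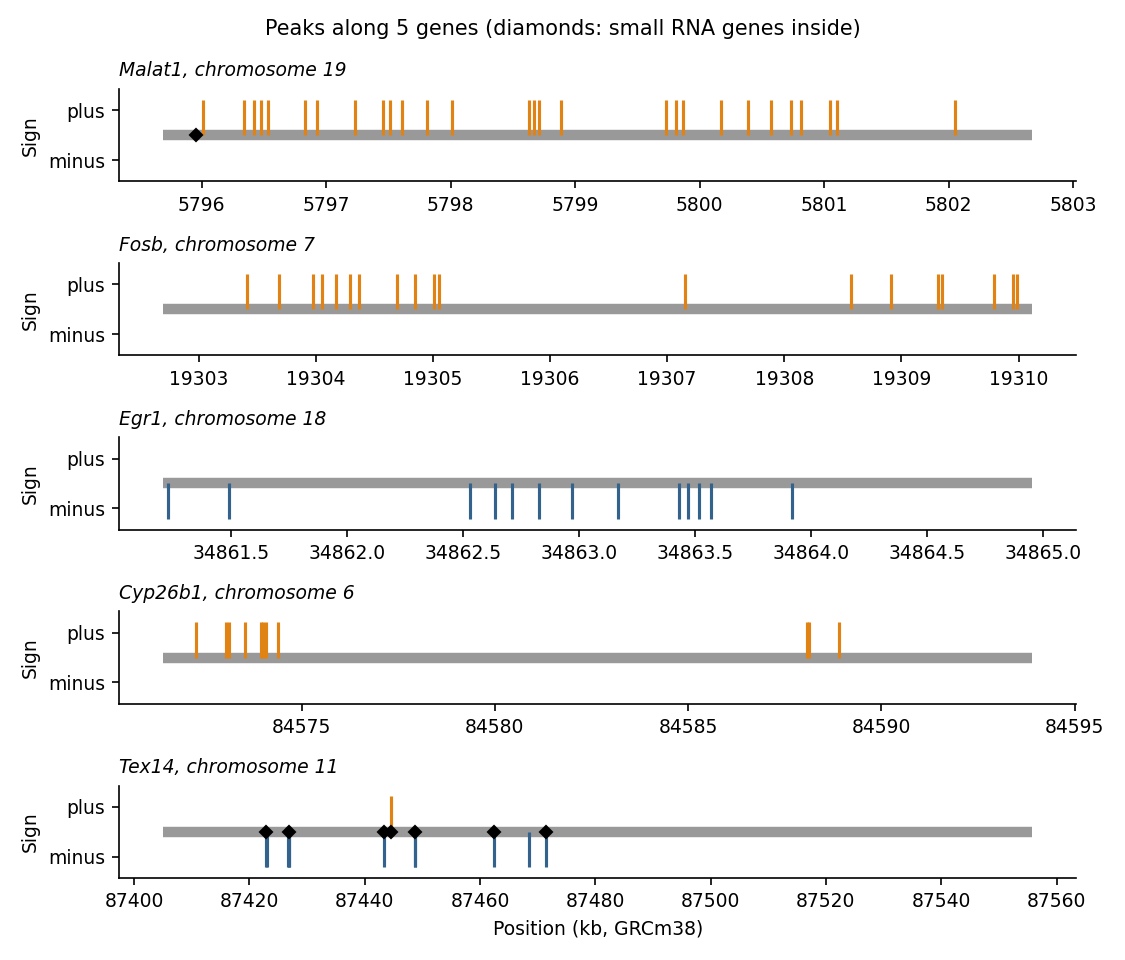
Position of each peak (vertical ticks) along Malat1, Fosb, Egr1, Cyp26b1 and Tex14, drawn as grey bars on mm10 coordinates in kb, with plus-sign peaks above and minus-sign peaks below the bar, and small RNA genes inside them as diamonds. Peaks spread over the whole of Malat1 with the plus sign alone, and 11 of the 12 peaks of Tex14 lie at its diamonds.

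Gene bodies held 10244 of the 15769 peaks (65.0%, interval 64.2 to 65.7), against 48.1% for positions redrawn at random on the same chromosomes, a 1.35-fold excess. Small structured RNAs showed the largest excess. Genes of rRNA, mostly 5S, held 87 peaks where 0.052 were expected, and 57 of 63 such genes had a peak. Peaks in tRNA genes numbered 89 against 0.175 expected, those in annotated snRNA genes 212 against 0.704, and those in snoRNA genes 93 against 1.01. Protein-coding genes held 8578 peaks, 1.36-fold over expectation, and long noncoding genes 1549 (9.82% of peaks against 8.55% in redraws). For each of these classes the permutation p was 0.0020, the smallest that 1000 redraws can give (2-sided, unchanged by Benjamini-Hochberg adjustment over 8 biotypes). Of 21887 protein-coding genes, 5583 (25.5%) had a peak, as did 1298 of 12727 long noncoding genes (10.2%). Among the 676 peaks of 40 nt or more, the protein-coding excess turned to 0.894-fold. Of those 676, 158 (23.4%) lay within 1 kb of small RNA genes, against 4.78% of all peaks. Reads of multi-copy RNA genes can map to several places, so the copy that gave rise to a peak is uncertain.

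Of the 18 structured RNAs listed by name before the data were examined, 16 were found in the gene table, and 14 of these held a peak. The 18S rRNA copy Rn18s-rs5 had 9, the 7SK RNA gene Rn7sk 5, Rmrp, the RNA of the mitochondrial RNA processing nuclease, 5, and the signal recognition particle RNA gene Rn7s2 3. Nuclear long noncoding RNAs with a peak numbered 11 of 17, with 52 peaks between them. Besides Malat1, the list held Neat1, the paraspeckle RNA, with 7 peaks (6.88-fold, adjusted exact Poisson p = 0.037) and Meg3 with 4 (16.3-fold, adjusted exact Poisson p = 0.047), while Airn held 2 and did not pass (adjusted exact Poisson p = 1). Of this list, 5 genes passed adjusted over the list alone and 3 over all genes tested. D230017M19Rik, a long noncoding RNA on chromosome 1, held 7 peaks (18.9-fold, adjusted exact Poisson p = 0.00017), but 5 of them lay in the snRNA genes Gm24497 and Gm25939, and without these it did not pass (7.20-fold, adjusted exact Poisson p = 1). The long noncoding gene 6530403H02Rik, on chromosome 3, also held 7 but did not pass (2.02-fold, adjusted exact Poisson p = 1). With the chromosome density alone the folds were 43.8 for Neat1, 45.7 for D230017M19Rik and 3.32 for 6530403H02Rik. With nearby peaks merged, D230017M19Rik fell to 3 peaks and did not pass (8.83-fold, adjusted exact Poisson p = 0.67). Meg3 kept its 4 peaks and its fold there, but its p crossed the threshold (adjusted exact Poisson p = 0.072).

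Among protein-coding genes grouped by function, splicing factor genes carried peaks more often than genes of like length, while the excess at ribosomal protein genes and snoRNA hosts was smaller away from small RNA genes. Cytoplasmic ribosomal protein genes had a peak in 28 of 74 (37.8%, interval 27.6 to 49.2) against 10.3% in 10000 length-matched random lists (permutation test, adjusted p = 0.0016). The share was 24.3% against 10.2% without peaks in small RNA genes (adjusted permutation p = 0.0064) and 10.8% against 9.92% without peaks within 1 kb of them (adjusted permutation p = 0.90). Among the 42 members with no small RNA gene within 1 kb it was 19.0% against 10.0% (adjusted permutation p = 0.19). Rpl4 and Rpl13a held 5 peaks each, and Rpl13 and Rpsa 3 each, of which 1, 4, 0 and 2 lay in snoRNA genes. Passing the test of excess peaks were 6 members adjusted over the list alone and 3 over all genes tested, of which Rpl4 alone passed without peaks in small RNA genes and none without peaks within 1 kb of them, where Rpl4 kept 0. With nearby peaks merged, Rpsa no longer passed (48.3-fold, adjusted exact Poisson p = 0.23). Hosts of snoRNAs and other small RNAs had a peak in 11 of 16 protein-coding members (68.8%, interval 44.4 to 85.8) against 20.2% (adjusted permutation p = 0.0016), and in 9 of 20 noncoding ones. Without peaks in small RNA genes it was 7 of 16 (43.8%) against 19.9%, still above it but not past the threshold (adjusted permutation p = 0.096), and without peaks within 1 kb of them 25% against 19.6% (adjusted permutation p = 0.88). Among plus-sign peaks alone it was 18.8% against 7.95% (adjusted permutation p = 0.67). Examples were Eif4a1 with 6 peaks (60.7-fold, 133-fold with the chromosome density alone, adjusted exact Poisson p = 3.2e-06), 4 of them outside small RNA genes, and Snhg5, Eef2 and Nop58 with 4 each, of which 1, 4 and 0 lay outside. Of the list, 14 members passed adjusted over the list alone and 7 over all genes tested, 2 of these without peaks in small RNA genes and 0 without peaks within 1 kb of them; with nearby peaks merged, Snhg5 no longer passed (135-fold, adjusted exact Poisson p = 0.067). Spliceosome and splicing factor genes had a peak in 22 of 47 (46.8%, interval 33.3 to 60.8) against 22.5% (adjusted permutation p = 0.0032), and still passed among the 43 members with no small RNA gene within 1 kb (44.2%, adjusted permutation p = 0.021). Srrm2, a scaffold of nuclear speckles, held 9 peaks (29.2-fold, adjusted exact Poisson p = 1.8e-07), Hnrnpk 5, and Hnrnpd and Hnrnpr 2 each; 3 members passed adjusted over the list alone and 2 over all genes tested. When at least 2 peaks were required, the ribosomal protein list stood at 8.11% against 2.18%, just short of the threshold (adjusted permutation p = 0.054). Most ribosomal protein genes, 59 of 74, have a named pseudogene, so their peaks are uncertain where reads map to several places.

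Germ cell lists and the retinoic acid list did not pass. Genes of differentiating spermatogonia had a peak in 12 of 24 (50.0%, interval 31.4 to 68.6) against 30.4% (adjusted permutation p = 0.11), among them Kdm5b with 3 peaks, Kit, the sorted surface receptor, with 2, Dmrt1 with 2 and Ddx4 with 1. Retinoic acid genes had a peak in 11 of 22 (50.0%, interval 30.7 to 69.3) against 29.3% (adjusted permutation p = 0.11); beside Cyp26b1, Rarb held 5 peaks, Stra6 3 and Aldh1a1 1. Undifferentiated spermatogonial genes stood at 10 of 27 (37.0%) against 26.3% (adjusted permutation p = 0.29), with 3 peaks in Gfra1, 2 each in Pax7 and Ret and 1 in Cdh1. Genes of meiotic initiation and prophase stood at 15 of 49 (30.6%) against 34.1% (adjusted permutation p = 0.77), and beside Tex14 the list held Stag3 with 3 peaks, Rec114 with 2 and Ankrd31 with 1. In the transposon and piRNA list, 5 of 19 genes had a peak (26.3%) against 33.7% (adjusted permutation p = 0.77), with 2 in Mov10l1, 1 of them in an snRNA gene, and 1 each in Morc1, Gtsf1 and Ddx4. Spermatid genes held 0 peaks in 28 genes (interval up to 12.1%) against 12.5% (adjusted permutation p = 0.090). Tex14 and Cyp26b1 alone among the members of these 6 lists passed the test of excess peaks, adjusted over the list alone and over all genes tested, and without peaks in small RNA genes only Cyp26b1 passed over all genes tested (adjusted exact Poisson p = 2.1e-12).

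Markers of other testis cells also carried peaks. Sertoli cell markers had a peak in 12 of 22 (54.5%, interval 34.7 to 73.1) against 29.4% (adjusted permutation p = 0.038), led by Tjp1 with 3 peaks, Clu and Dmrt1 with 2 each and Aard with 1. Dmrt1 is in the list of differentiating spermatogonia as well. With at least 2 peaks required the Sertoli share was 13.6% against 11.3% and did not pass (adjusted permutation p = 0.99), and none of its members passed singly. Among plus-sign peaks alone the share was 9.09% against 13.2%, below expectation. Among minus-sign peaks alone it was 50% against 22.2% (adjusted permutation p = 0.022). The list also fell short without peaks within 1 kb of small RNA genes (adjusted permutation p = 0.061) and among genes with no small RNA gene within 1 kb (adjusted permutation p = 0.079), its share unchanged in both and the expected share 28.8% and 28.7%. Leydig and interstitial markers had a peak in 9 of 20 (45.0%) against 22.6% (adjusted permutation p = 0.090), with 2 in Col3a1 and Nr2f2 and 1 in Col1a2 and Cyp17a1. Mast cell, macrophage and endothelial markers had a peak in 3 of 19 (15.8%) against 30.3% (adjusted permutation p = 0.27), 1 each in Csf1r, Egfl7 and Vwf.

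Genes of the exosome and its cofactors had a peak in 8 of 30 (26.7%) against 24.2% (adjusted permutation p = 0.89), with 2 in Pabpn1, Zcchc7 and Zfc3h1 and 1 in Dis3. Cleavage and polyadenylation genes stood at 13 of 28 (46.4%) against 28.7% (adjusted permutation p = 0.11), with 3 peaks in Fip1l1 and 2 each in Cpsf2, Cstf1 and Papola. Chromatin regulators stood at 21 of 36 (58.3%) against 44.8% (adjusted permutation p = 0.20); Atrx held 5 peaks and passed singly (11.7-fold, adjusted exact Poisson p = 0.034), while Ash1l, also with 5, and Arid1a and Arid1b, with 3 each, did not. Mitotic cell cycle genes stood at 12 of 34 (35.3%) against 24.4% (adjusted permutation p = 0.26), with 3 peaks in Ccne2, 2 in Anln and 1 each in Cdk6 and Rrm1; Ccne2 passed adjusted over the list alone and not over all genes tested (adjusted exact Poisson p = 0.13). With nearby peaks merged, Atrx no longer passed (9.56-fold, adjusted exact Poisson p = 0.25), nor did it without its 2 peaks in the snRNA gene Gm26020 (7.12-fold, adjusted exact Poisson p = 0.91).

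**Figure D3:**
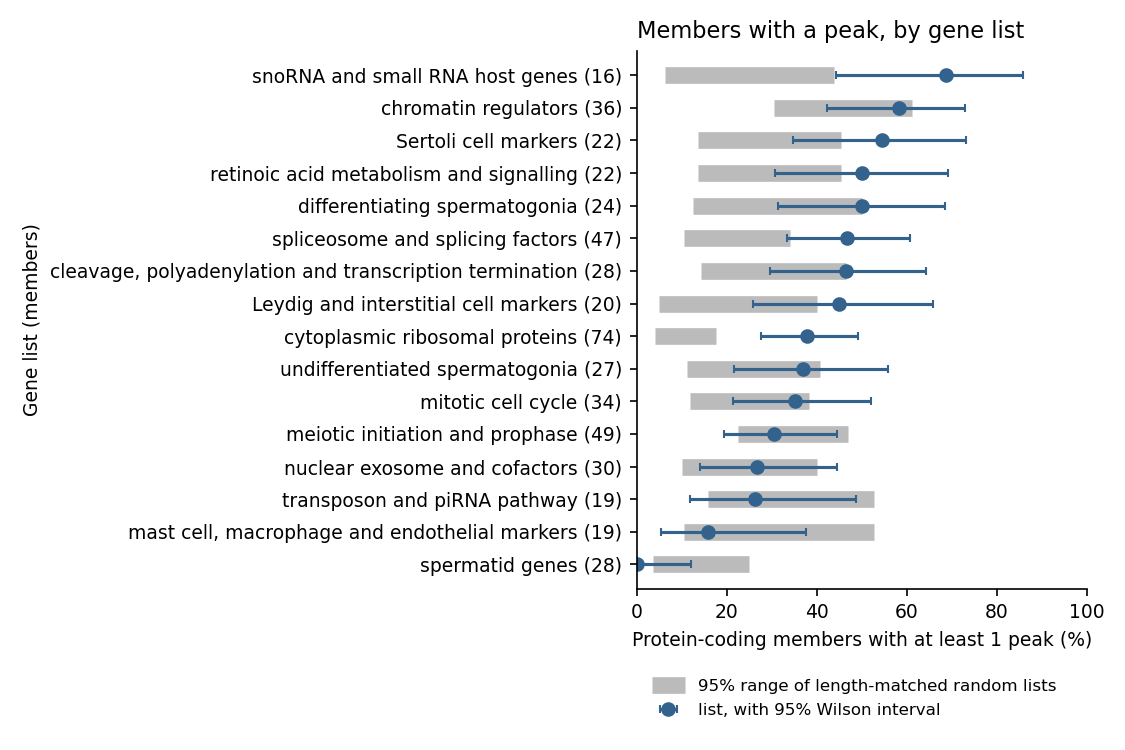
Share of the protein-coding members of each gene list with at least 1 peak (points, %, with 95% Wilson intervals), beside the range that holds 95% of length-matched random lists (grey bars). The snoRNA host list at 68.8% and the ribosomal protein list at 37.8% lie above their random ranges with peaks in small RNA genes counted, and the spermatid list lies at 0.

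Peaks gathered near the ends of genes. Within 1 kb of an end of a protein-coding gene lay 2781 peaks (17.6%, interval 17.0 to 18.2) against 3.10% for redrawn positions, a 5.68-fold excess that was 3.43-fold among peaks of 40 nt or more (permutation p = 0.0020, the smallest that 1000 redraws can give). Of these, 2142 lay inside the gene and 639 outside. Density was 67.3 peaks per Mb in the first 250 nt inside a gene end and 37.2 in the first 250 nt outside it, against 8.12 and 5.33 per Mb between 4750 and 5000 nt away. Along protein-coding and long noncoding genes over 1 kb, the first and last 10% of the length together held 3376 of 9654 peaks (35.0%, interval 34.0 to 35.9). With each peak given a random 10% step of its gene instead, the share was 20% (permutation p = 0.0020). Start and end of the transcript could be set apart only by the sign in the file, which is opposite to the known orientation of Malat1, Neat1, Actb, Fosb, Fos, Egr1 and Ubb. Read against the sign, the first 10% held 1622 of these peaks and the last 10% held 1754, so the first took 48.0% of both (interval 46.4 to 49.7, exact binomial p = 0.024). This small difference was not past the threshold among minus-sign peaks alone (48.7%, exact binomial p = 0.23). Over all protein-coding genes, only 64.4% of peak pairs in a gene shared a sign, where chance gives 54.9%. A sign that follows the transcript so weakly moves any split toward even, by an amount that was not worked out. The split therefore cannot tell whether peaks lay at the start or the end of transcripts.

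**Figure D4:**
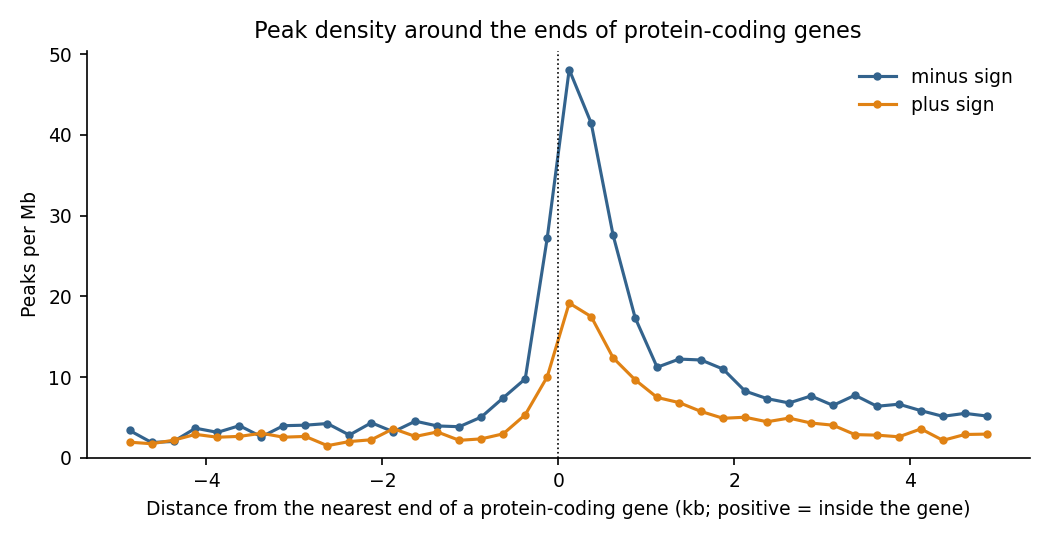
Peaks per Mb (vertical axis) in 250-nt steps by distance in kb from the nearest end of a protein-coding gene, positive inside the gene, for minus-sign (blue) and plus-sign (orange) peaks. Both curves rise at the gene end, and the sum of both is 67.3 per Mb in the first 250 nt inside.

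Regions just outside protein-coding genes were examined for transcripts running away from the gene, since transcripts that arise upstream of promoters are known exosome substrates. Up to 3000 nt beyond the gene, 830 peaks were found outside other genes. Read against the sign, 50.1% pointed away from the gene (interval 46.9 to 53.3, averaged over both sides), and the sign did not depend on the side (Fisher's exact test, p = 1). Minus-sign peaks prevailed on both sides, 311 against 152 at the lower coordinate and 247 against 120 at the higher. Without the strand of genes, upstream and downstream flanks were pooled. The test therefore cannot decide whether transcripts upstream of promoters were bound.

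The sex chromosomes carried few peaks. X held 555 peaks, 3.25 per Mb and 0.557 of the number expected from its size, and Y held 90, 0.991 per Mb and 0.170 of it (adjusted permutation p = 0.00038 for both). Male cells carry a single copy of each. Bases and gene copies to which reads cannot be uniquely placed were not left out of the expected numbers. A true scarcity of contacts therefore cannot be told from lost reads. The value of Y was 0.0877 when its 7 peaks in genes were set against its number of genes, 0.102 among minus-sign and 0.278 among plus-sign peaks, each past the threshold. Chromosome 11 had the highest density at 8.24 per Mb, and chromosome 3 the lowest among autosomes at 4.88. On X, the deficit did not pass among the 30 peaks of 40 nt or more (0.703 of expectation, adjusted permutation p = 0.16).

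More peaks had the minus than the plus sign, 9664 against 6105 (61.3% minus, interval 60.5 to 62.0, exact binomial p = 4.1e-178). All 19 autosomes lay above 50%, between 56.7% and 67.8%. X stood at 53.5% (interval 49.4 to 57.6) and Y at 36.7% (27.4 to 47.0). The minus share was 69.9% within 1 kb of gene ends and 59.4% elsewhere (Fisher's exact test, adjusted p = 7.0e-25). In the 93 genes above background it was 45.5%, against 64.1% in other genes (Fisher's exact test, adjusted p = 5.2e-15). This test counted each peak as independent, but peaks within these genes mostly shared a sign, so its p-value is too small. By gene, 33 of the 93 had minus-sign peaks alone and 33 had plus-sign peaks alone. Peaks of 40 nt or more did not share the excess (49.3% minus).

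The 10 widest peaks fell in ribosomal RNA, in protein-coding and long noncoding genes and outside genes. The widest, of 760 nt, and another of 340 nt lay at Rn18s-rs5 on chromosome 17. A peak of 560 nt lay where Filip1l and Cmss1 overlap on chromosome 16 (57391101 to 57391660), 1 of 420 nt in Zc3h7a (chromosome 16, 11143861 to 11144280), and 1 each of 380 nt in Peak1 (chromosome 9) and in the long noncoding gene Gm36876 (chromosome 11). Kcnip1 held a peak of 360 nt and Jarid2 1 of 340 nt, and 2 peaks of 340 nt lay outside annotated genes on chromosomes 1 and 8. The densest window of 100 kb, on chromosome 8 from 123500000 to 123599999, held 72 peaks in the 5S rRNA gene cluster, and the next, on chromosome 17 from 39800000 to 39899999 around Rn18s-rs5, held 47. Among the other windows with the most peaks were those of Malat1 with 24 and of Fosb with 23. A window on chromosome 5 from 25900000 to 25999999 held 21 peaks, all minus, among them 4 each in the predicted genes Gm21168 and Gm21698.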

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

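All settings by sign, width or small RNA genes, and all settings of the Poisson test, were chosen after seeing the data. Of the results that answer a question of the report, 149 recomputed values kept direction and side of the threshold, 14 fell short of it, 7 changed direction and 10 counts moved by over 1.5 times. The genic excess stayed between 1.28-fold and 1.39-fold and the excess near gene ends between 3.43-fold and 7.58-fold in every setting run. No paired analysis was possible because all samples form 1 group, and for the same reason, with 1 list, no replicate could be left out. Planned but not run, for want of a score, exons or strand, were the higher-scoring peaks, exons alone, other class orders and transcripts, and every alternative of the tests not run. The missing depth and the 20-nt grid limit all results; unless construction shows it, the cause was not tested.

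With the 676 peaks of 40 nt or more, the protein-coding excess became 0.894-fold (permutation p = 0.027), the long noncoding 1.26-fold, the share of the first against the last 10% of genes 49.4%, X 0.703-fold and the minus share 49.3%. In that setting, with far fewer peaks to place, 2 lists passed in place of 4. Shares were 0% for undifferentiated and differentiating spermatogonia, Sertoli (expected 1.11%), Leydig, exosome, cleavage and retinoic acid lists. They were 2.04% for meiotic (expected 1.25%), 2.13% for splicing (0.706%) and 5.26% for piRNA genes. The meiotic share thus lay above the expected value instead of below it, and the splicing share stayed above it without passing.

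Requiring 2 peaks left 2 lists, with Sertoli at 13.6% (expected 11.3%), ribosomal at 8.11% (2.18%) and cell cycle at 5.88% (6.73%). Plus-sign peaks alone left 2, with Sertoli at 9.09% (expected 13.2%), undifferentiated at 7.41% (11.4%), exosome at 6.67% (9.46%), snoRNA hosts at 18.8% (7.95%) and piRNA at 21.1% (14.0%). Without length matching 9 lists passed, and the shares of meiotic (30.6%) and piRNA genes (26.3%) lay above the expected value instead of below it. Minus-sign peaks alone gave a share of 48.7% in the first against the last 10% of genes.

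Without peaks within 1 kb of small RNA genes 1 list passed, the splicing factors, with Sertoli at 54.5% (expected 28.8%), ribosomal at 10.8% (9.92%) and snoRNA hosts at 25% (19.6%). That setting also takes away stretches of the host genes themselves. Among genes with no small RNA gene within 1 kb, 1 list passed, with Sertoli at 54.5% (28.7%) and ribosomal at 19.0% (10.0%); the snoRNA hosts, with 1 member left, gave no value. Without peaks in small RNA genes the snoRNA hosts stood at 43.8% (19.9%), and the folds of Tex14 (0.829) and Nop58 (0) fell below 1, because their peaks lay in such genes.

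The share pointing away from genes, 50.1%, fell below 50% with merged peaks (49.1%), 1000-nt flanks (47.9%) and any overlap (49.9%) and was 67.5% among 30 peaks of 40 nt or more, never past the threshold. Genes above background, 93, became 183 with the chromosome density alone (93 shared), 53 with merged peaks (53 shared), 35 with minus-sign peaks (33 shared) and 20 with peaks of 40 nt or more (11 shared). The folds of Vwf (1.31), Ankrd31 (1.03) and Zcchc7 (1.61) rose above 1 with the chromosome density, as did Zcchc7 with merged peaks (1.14). Ccne2 (29.5-fold) and Rpl13 (149-fold), which did not pass over all genes tested, passed with the chromosome density alone.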

Other observations

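The lists of immediate early and heat shock genes were drawn up after Fosb, Egr1, Fos and Nr4a1 had been seen, before the peaks of their other members; the tests of the sign and of long genes were chosen only after those results were seen. Immediate early genes respond within minutes to stimuli and give short-lived mRNAs. Of the 40 not seen before the test, 19 (47.5%, interval 32.9 to 62.5) had a peak, against 14.6% in length-matched random lists (permutation test, adjusted p = 0.00030). Beside those 4 genes, Jun and Zfp36 held 4 peaks each, Btg2, Ccn1, Fosl2 and Jund 3 each, and Atf3, Ier5, Junb, Myc, Nr4a3 and Per1 2 each. Arc, Dusp1, Egr2, Ier3 and Socs3 held 0. Heat shock genes had a peak in 6 of 14 (42.9%, interval 21.4 to 67.4) against 14.2% (permutation test, adjusted p = 0.016), with 3 in Hsp90ab1 and Hspa8 and 2 in Hspe1. All 3 of Hspa8 lay in snoRNA genes inside it, and without peaks in small RNA genes the list did not pass (5 of 14, 35.7% against 13.9%, permutation test, adjusted p = 0.068). Hspa1a and Hspa1b, which are near-identical copies and therefore uncertain, held 0.

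Other short protein-coding genes above background, picked after their values were seen, included Eef1a1, a translation factor, with 4 peaks (175-fold, adjusted exact Poisson p = 2.1e-05), Fth1 and Ftl1, the ferritin chains, with 3 each (adjusted p = 0.0095 and 0.018), and the chromatin protein Hmgn2 with 3 (adjusted p = 0.015). Replication-dependent histone genes were represented by H4c1 with 3 peaks and H4c9, H4c6 and H4c3 with 2 each. These histone genes are near-identical copies, so their peaks are uncertain. Sharing of the sign varied with gene length. In protein-coding genes of up to 5 kb, 7.43% of genes had a peak, density was 45.8 per Mb, and 91.6% of peak pairs in a gene shared a sign (bootstrap interval over genes 81.0 to 96.0, chance 52.2%). The share was 79.5% from 5 to 20 kb, 72.0% from 20 to 50 kb, 57.6% from 50 to 100 kb (interval 53.1 to 61.8, chance 54.1%) and 61.7% from 100 to 300 kb (interval 57.7 to 65.4, chance 54.6%). Pairs were pooled over genes, so genes with many peaks weigh most. Among them, all with peaks of a single sign, were Egr1, Actb, Ubb and Fos up to 5 kb and Fosb from 5 to 20 kb. The trend with length may therefore rest largely on a few genes.

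Immediate early genes among the genes with the most peaks may reflect a stress or dissociation response that raised these transcripts as a class during sorting. The 40 members not seen before the test had 2 or more peaks in 30% (interval 18.1 to 45.4), above the 10% at the upper end of the 95% range of random lists. A preference of MTR4 for short-lived nuclear RNA predicts the same, and no biological explanation was tested, since no other condition was there to compare. Transcript abundance alone predicted that ribosomal protein genes would reach the same share; they reached 8.11% (6 of 74 against 12 of 40, Fisher's exact test, p = 0.0056). The rule written beforehand would have excluded abundance, but it was set aside after the result was seen. The reason was that 79.7% of ribosomal protein genes have a named pseudogene against 2.50% of the unseen genes. Reads of ribosomal protein genes may therefore be lost, but such a loss was not tested. Against a general loss, 57 of 63 rRNA genes had a peak, so reads of multi-copy genes were not all dropped. Expression is not given, so abundance and preference cannot be told apart.

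The minus-sign excess of 61.3%, not shared by peaks of 40 nt or more (49.3%), could not be set against the strand of genes, which was not used here. A few loci with many peaks are argued against, since with 1 peak kept per 100-kb window and sign the minus share was 59.5% (interval 58.6 to 60.4). Reads of multi-copy small RNA genes are argued against as well, since it was 61.9% (interval 61.2 to 62.7) without peaks near such genes. Unequal treatment of the strands in alignment, calling or filtering could account for the excess and stays open: the lowest share among the 20 chromosomes with at least 100 peaks was 53.5% on X, with an interval that spans 50%, and Y, which that minimum, set after the data were seen, leaves out, stood below 50% (36.7%, interval 27.4 to 47.0, 90 peaks). No biological explanation was tested.

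Peaks on both strands of long genes were the third pattern. In protein-coding genes over 300 kb, 84.6% had a peak, at 4.17 per Mb, and 58.1% of peak pairs shared a sign (bootstrap interval 54.7 to 61.7) where chance gives 55.0%. Peaks placed without regard to transcripts would give the chance value and the density outside genes, 3.79 per Mb; since the interval holds the chance value, such peaks and sparse true contacts cannot be told apart there. In genes of up to 50 kb and of 100 to 300 kb the interval lay above chance, so that explanation cannot cover all peaks there. No biological explanation was tested.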
